A study of Rattus norvegicus with 18 samples.

How the data were processed

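RNA was measured by bulk RNA sequencing in intestinal tissue of 18 Sprague-Dawley rats, an outbred laboratory stock, in 3 groups of 6. Per the labels' protocols, control rats received no treatment, irradiated rats received a single X-ray dose of 10 Gy, and a further group received the same dose followed by Changbing Formula, and libraries were made from poly(A)-selected RNA primed with random hexamers. The labels name the tissue only as intestine, without a segment, and give no sex, time after irradiation or hour of collection. All 18 free-text descriptions carry the same wording for untreated rats, which goes against the titles and treatment fields of 12 samples, and groups were taken from the titles. All samples carry the same batch label.

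The deposited table holds raw counts per gene, made per the file headers with featureCounts 2.1.1 on paired-end alignments to mRatBN7.2 with Ensembl annotation release 110. FastQC, fastp, STAR and SAMtools are named in the submitters' processing notes, with versions not given in the sources used here. Per the file headers, both ends had to be aligned and chimeric pairs were left out, and no option for counting read pairs or for strand was set. Between 66.9% and 74.6% of the counts from 1 to below 40 in each library were even numbers, so the deposited counts largely count both reads of a pair and counting error is larger than their size implies. Without strand, reads of overlapping genes on opposite strands cannot be told apart. No count was normalized before deposit, per the file headers, and 0 columns of per-sample values were left unused. Library totals were between 33598572 and 48398184 counts.

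The table identifies its 30562 genes by Ensembl ID and does not pair them with symbols. The gene table used beside it matched 0 of these IDs, so the 42 gene lists fixed before the data were examined, and the set tests on them, could not be run, and genes are given by ID only. The rule for named genes, fixed before the data were examined, needed symbols. In its place the gene with the lowest p in each direction of each comparison was taken, among genes with a mean of at least 1 CPM (counts scaled to the library total) over the 12 libraries compared, which gave 4 IDs. That substitute was chosen after the data were seen.

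Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, in a single model of all 18 libraries without covariates, after filterByExpr had kept 16593 genes and TMM factors had been computed. Each p was adjusted by the Benjamini-Hochberg method over these genes, and genes with an adjusted p below 0.05 were counted. Per-library values are TMM-scaled CPM. Standard errors of log2 fold changes were derived from the test, as the absolute log2 fold change divided by the square root of its F statistic. These errors, and the 95% intervals built on them, are therefore approximate. Principal components and distances between groups used log2 CPM with a prior count of 2. Distances were compared with an exact permutation test over 924 arrangements of 12 libraries. Genes of each chromosome were tested as sets with camera in limma 3.58.1 at a preset correlation of 0.01, a choice made after the data were seen. A gene was called library-specific where a library had at least 10 CPM and at least 32 times the median of the 18 libraries (taken as at least 0.1 CPM), thresholds also chosen after the data were seen.

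The procedure was tested on simulated counts with changed genes. For irradiated against control, in a fit of 16593 genes, it recovered 17.9% of 67 genes changed 2-fold. It recovered 73.1% of 67 changed 4-fold and 83.3% of 66 changed 8-fold, all with a mean of at least 1 CPM. Noise was drawn for each gene separately, without libraries that depart from the others across many genes. Recovery in the real data, which hold such libraries, may therefore differ. The alternatives tried were other scalings, other filters, DESeq2 1.42.0, limma-voom with sample quality weights, fits of 12 libraries, a replicate term, and each library left out. No pair of libraries agreed within sampling noise: the lowest median chi-square over 153 pairs was 7.29, where sampling gives 0.455 for independent reads and 0.910 if every read were counted with its mate. The p-values measure the spread between rats as far as each library is a separate animal, which the labels imply but do not state.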

Results

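Gene expression was compared in intestinal tissue of control rats, rats given 10 Gy of X-rays, and rats given the same dose and then Changbing Formula, a treatment named in the labels, with 6 libraries in each group. Total counts averaged 43287921 ± 5412430 in control, 40145851 ± 4659327 in irradiated and 39450090 ± 3362559 in irradiated plus formula libraries (SD, n = 6). Genes on the mitochondrial chromosome took 19.5% ± 5.34 of the counts in control, 19.9% ± 12.0 in irradiated and 22.4% ± 3.30 in irradiated plus formula libraries (SD, n = 6), and no difference in these shares passed a two-sided exact permutation test (p = 0.937 for irradiated against control, adjusted p = 0.937 over 9 tests). A single gene on that chromosome, at 5323 to 6867 on the forward strand, took between 2.47% and 18.5% of all counts in a library.

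The libraries did not separate by group. The first principal component held 40.2% of the variance and set control 2, at 176, and irradiated 4, at 216, apart from the other 16 libraries, which lay between -52.9 and 34.2. Group membership accounted for 10.9% of the variance in log2 CPM (permutation p = 0.514, 100000 permutations). Within groups the Spearman correlation between libraries had a median of 0.951 in control, 0.918 in irradiated and 0.949 in irradiated plus formula.

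**Figure D1:**
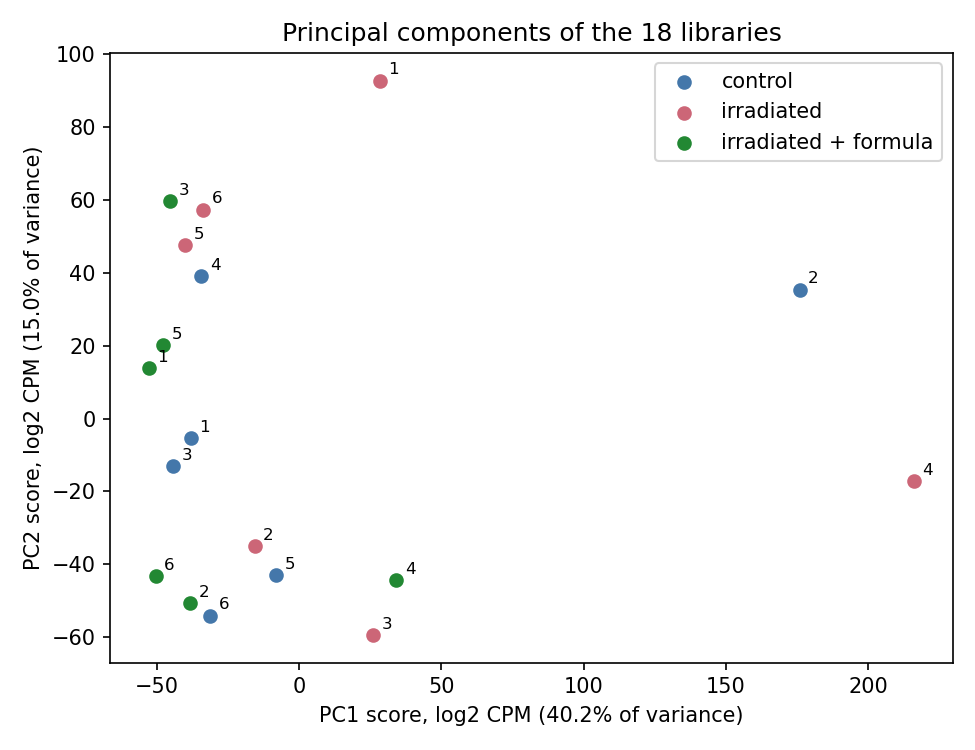
Scores of the 18 libraries on the first and second principal components of log2 CPM, coloured by group and numbered by replicate. Control 2 and irradiated 4 lie at 176 and 216 on the first component, and the other 16 libraries lie between -52.9 and 34.2.

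The first comparison asked what irradiation changed. No gene passed the threshold between irradiated and control libraries in edgeR's quasi-likelihood test: 0 genes were higher and 0 lower, and the lowest adjusted p was 0.998. At an unadjusted p below 0.05 there were 321 genes, where chance gives 830, and DESeq2 and limma-voom also called 0. That number rested on single libraries: it was 2130 without control 2, 160 without control 3, 177 without control 6 and 503 without irradiated 4, and limma-voom with quality weights gave 1818. The lowest edgeR adjusted p was 0.388 without control 2, 0.493 without irradiated 1, 0.377 without irradiated 4 and 0.110 with these 3 libraries left out together. ENSRNOG00000014448, at 167331633 to 167430231 on the forward strand of chromosome 1 (mRatBN7.2), had the lowest p among genes with a higher level, with 38.9 ± 14.4 CPM in irradiated and 17.8 ± 5.68 CPM in control libraries (SD, n = 6; log2 fold change 1.13, SE 0.27, edgeR adjusted p = 0.998). ENSRNOG00000021027, at 96175440 to 96180745 on the forward strand of the same chromosome, had the lowest p among genes with a lower level, with 40.5 ± 27.6 CPM in irradiated and 141 ± 70.1 CPM in control libraries (SD, n = 6; log2 fold change -1.80, SE 0.44, edgeR adjusted p = 0.998). Neither passed the test. The 95% interval of the fold change lay within 2-fold in either direction for 50.8% of the 16593 genes tested, so changes of that size were not excluded for the remaining genes.

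The second comparison asked what the formula changed in irradiated rats. Again 0 genes passed in edgeR, with a lowest adjusted p of 0.445 and 928 genes at an unadjusted p below 0.05, while DESeq2 called 2 higher and 6 lower and limma-voom called 0. The number at an unadjusted p below 0.05 was 535 without irradiated 4, 1412 without irradiated 5, 1447 without irradiated plus formula 4 and 571 without irradiated plus formula 6, where chance gives 830, and it was 411 with control 2, irradiated 1 and irradiated 4 left out. The lowest edgeR adjusted p was 0.130 without irradiated 3, 0.766 without irradiated 1 and 0.9999 without irradiated 4, and it was 0.896, 0.836, 0.764 and 0.930 without irradiated plus formula 1, 2, 5 and 6, each left out in turn. ENSRNOG00000039858, at 8347314 to 8353988 on the reverse strand of chromosome 7, lay between 9.54 and 13.6 CPM in the 6 libraries with the formula and between 3.37 and 7.09 CPM in the 6 without it (log2 fold change 1.20, SE 0.21, edgeR adjusted p = 0.445). Its exons overlap those of 1 other annotated gene, so its count is uncertain. ENSRNOG00000055408, at 110595091 to 110601473 on the forward strand of chromosome 7, stood at 1.11 ± 0.26 CPM with the formula and 2.87 ± 0.93 CPM without it (SD, n = 6; log2 fold change -1.37, SE 0.27, edgeR adjusted p = 0.729). Both, and ENSRNOG00000021027, were among the DESeq2 calls, with DESeq2 adjusted p of 4.0e-05 for ENSRNOG00000039858, 0.00059 for ENSRNOG00000055408 and 0.017 for ENSRNOG00000021027. In all other alternatives these 3 genes stayed short of the threshold, with adjusted p up to 0.9999. The 17 tested genes of the mitochondrial chromosome were the only chromosome set past the threshold in camera (adjusted p = 0.0090, 16 members with a higher and 1 with a lower fitted value, median log2 fold change 0.16), and the call was lost with an estimated correlation (adjusted p = 0.885).

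The third comparison set irradiated plus formula against control, and here 1 gene rose and 1 fell in edgeR's quasi-likelihood test. ENSRNOG00000014448 rose from 17.8 ± 5.68 to 81.0 ± 15.4 CPM (SD, n = 6; log2 fold change 2.19, SE 0.27, edgeR adjusted p = 0.0029), and all 6 libraries with the formula, at 57.7 to 104 CPM, lay above all control libraries, at 12.4 to 25.9 CPM. ENSRNOG00000021027 fell from 141 ± 70.1 to 10.4 ± 3.79 CPM (SD, n = 6; log2 fold change -3.76, SE 0.47, edgeR adjusted p = 0.0029), from 59.9 to 263 CPM in control to between 5.38 and 14.9 CPM with the formula. The irradiated means, 38.9 and 40.5 CPM, lay between those of the other groups for both genes. In all, 81 genes were higher and 57 lower without any overlap between the groups, 138 against a mean of 35.9 (0.216% of genes) by chance, and 22 of the 462 splits of these libraries gave 138 or more, up to 778. With a replicate term the model called 1 gene, ENSRNOG00000021027 (adjusted p = 0.040), and ENSRNOG00000014448 no longer passed (edgeR adjusted p = 0.061), with a log2 fold change of 2.20 and an SE of 0.30. DESeq2 called 47 genes and limma-voom with quality weights 499.

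**Figure D2:**
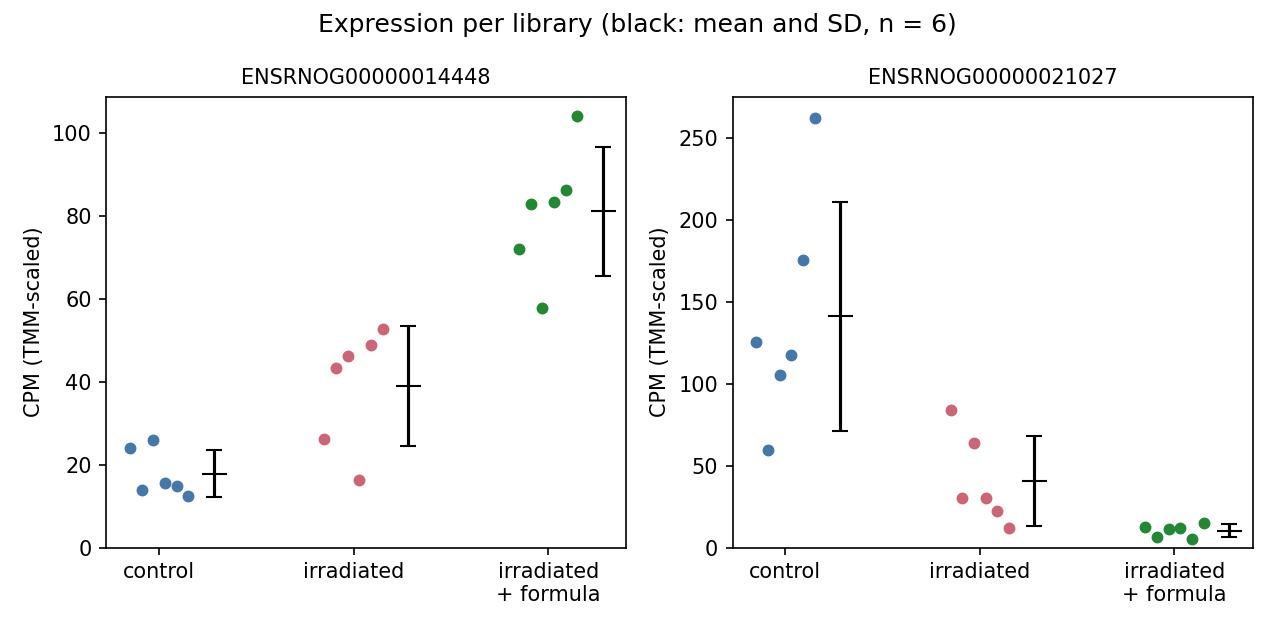
TMM-scaled CPM of the 2 genes called between irradiated plus formula and control, 1 point per library, with the mean and SD of each group (n = 6) in black. ENSRNOG00000014448 averaged 17.8, 38.9 and 81.0 CPM and ENSRNOG00000021027 averaged 141, 40.5 and 10.4 CPM in control, irradiated and irradiated plus formula libraries.

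Whether the formula moved the irradiation-responsive genes back could not be computed as planned, since 0 genes were called between irradiated and control. Across all tested genes, which are not independent replicates, the fold changes of the first and second comparisons had a Pearson r of -0.59 and a covariance of -0.156. Both contain the irradiated libraries, and 20 draws of simulated counts without any effect gave a mean r of -0.50 and a mean covariance of -0.160. The simulated r lay between -0.53 and -0.47, and the observed r was below that range. With permuted group labels the median r was -0.53, and 37 of 100 draws, which ranged from -0.91 to 0.22, were at least as low as the observed value. With irradiated 1, 3 and 5 in the first comparison and 2, 4 and 6 in the second, r was 0.03, and with these exchanged it was -0.16, both inside the range of -0.66 to 0.63 with permuted labels.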

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

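Of the tests on library-specific genes, those of irradiation and of tissue makeup were chosen after the result was seen. Control 2 had 309 library-specific genes and irradiated 4 had 348, each far from the other libraries of its group, as were their scores of 176 and 216 on the first principal component. Irradiated plus formula 4 stood apart from its own group by smaller amounts, with 32 library-specific genes and a score of 34.2. These are 6 of 27 group checks, where chance gives about 1.35. Both measures flagged the same libraries, so the flags are not independent and the excess is overstated. Irradiated 1 had 93 such genes without standing apart by that rule, and the other 15 libraries had between 0 and 37.

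Library-specific genes were counted again with every library thinned to the lowest total. The lowest count among control 2, irradiated 1 and irradiated 4 was then 93, and the highest of the other 15 was 35. Leaving out the mitochondrial chromosome gave 92 and 34. Neither test had much room to move the counts, since the rule uses CPM and a 32-fold threshold. Library totals lay between 33598572 and 48398184 counts and mitochondrial shares between 5.77% and 39.7%. The counts of irradiated and control libraries did not separate in a two-sided exact permutation test (p = 0.489), which leaves a part of irradiation open, and control 2 was not irradiated. Control 2 and irradiated 4 shared 210 of these genes and control 2 and irradiated 1 shared 74, where independent sets of their sizes would share 8.97 and 2.40, and irradiated 1 and irradiated 4 shared 17 against 2.70, all 17 also in control 2. Irradiated plus formula 4 shared 29 of its 32 with irradiated 4 and 28 with control 2, and irradiated 3 shared 26 of its 37 with irradiated 4, where 0.929, 0.825 and 1.07 would be shared. All these expected numbers assume draws from the 11985 genes with at least 10 CPM in some library. Genes with a high median can hardly reach 32 times that median, so the expected numbers are too low by an amount not measured. A different makeup of the tissue piece may be the source, but without gene symbols no cell type marker could be examined, and that explanation cannot be told apart from others.

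Of the tests on the 2 genes called between irradiated plus formula and control, the one leaving out libraries and the scaling without the mitochondrial chromosome were chosen after seeing the data. The other splits examined did not give this result. Of 100 splits, a sample of the 462 of the 12 libraries, only the real one called as many as 2 genes. The highest of the others was 0, and the remaining splits were not examined. Without control 2, irradiated 1 and irradiated 4, each fold change kept at least 98.7% of its log2 size, and under 3 other scalings at least 98.3%. Of those libraries only control 2 is among the 12 compared, so leaving them out had little room to move the fold changes. The same holds for the scalings, since the mean TMM factor was 1.01 in control and 0.984 in irradiated plus formula libraries. Within groups the genes had a Pearson r of -0.28 (permutation p = 0.365) and a Spearman rho of -0.32 (permutation p = 0.248) over 18 libraries, and r was -0.39 without control 3 and irradiated 4. An unlabelled variable that differs between animals, such as the hour of collection, could also move both genes, and that cannot be told apart from the treatment here, since no label records one. What the genes encode is not established here, so whether their levels depend on the hour of collection was not examined.

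The limma-voom count of 499 was reached by 4 of the 100 splits examined, the real one included. That is a share under 0.05, but the 100 are a sample of the 462 possible splits. The share over all of them was not measured and may be 0.05 or more. The highest count among the others was 1487 genes, several times the real count, while edgeR called 0 in the splits with that count. Whether this comes from a structure of the samples that the groups do not give or from the error control of the weighted fit was not tested. For the comparisons with a real count of 0, all 100 of 100 splits reach that count by construction, so they say nothing about chance. The highest count among them was 2390 for irradiated against control and 2 for irradiated plus formula against irradiated. The split with 2390 had control 2, control 5 and irradiated 1, 2, 3 and 4 on one side. On the first principal component all of these scored above the libraries on the other side. Other splits examined with control 2, irradiated 1 and irradiated 4 together called 0 genes, or 1 in a single split.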

How the results depend on the processing

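Settings that leave out named libraries together, the robust fit and the fit without the mitochondrial chromosome were chosen after seeing the data. Between irradiated and control all 25 alternatives gave 0 genes. Between irradiated plus formula and irradiated 24 of 25 gave 0, and DESeq2 gave 8. Between irradiated plus formula and control, against 2 genes, DESeq2 gave 47, limma-voom with quality weights 499, the fit of only the 12 libraries 6, and leaving out control 2 and irradiated 4, or these and irradiated 1, gave 7 each; the cause was not tested. Leaving out 1 library each gave 2 to 5, and 5 was without control 2. Both called genes stayed past the threshold in all these, and ENSRNOG00000014448 lost it only with the replicate block, which gave 1 gene and left its log2 fold change at 2.20 against 2.19, with an SE of 0.30 against 0.27. Same-numbered libraries showed no clear tendency to deviate together: 5 of 18 pairs had a correlation over 0.1, in a range from -0.51 to 0.61. Of 18 libraries, 4 correlated best with their own number. The lack of such a tendency across all genes cannot exclude that the numbers pair the rats. The set tests on gene lists were not run for want of symbols, and the reversal share had no called genes under any alternative tried. The biological coefficient of variation was 60.8%.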

Other observations

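The tests here were all chosen after the data were seen, except the counts over splits. Neighbours were taken among genes with at least 10 CPM in some library, so other annotated genes may lie between them. On that count library-specific genes were neighbours more often than shuffled genes: irradiated 4 had 113 neighbouring pairs, where 1000 shuffles gave at most 25. Control 2 had 65 against at most 17. The shuffles included genes whose high median hardly lets them pass, so the shuffled numbers are too low by an amount not measured. A run of 14 such genes in irradiated 4 lay at 101302918 to 102714551 on chromosome 4 (mRatBN7.2), with a summed level of 3377 CPM there, 2141 CPM in control 2 and a median of 83.4 CPM over the 18 libraries, while irradiated 1 had 64.7 CPM and the highest of the other 15 libraries 476 CPM. A run of 12 lay at 133764540 to 134628048 on chromosome 6, with 294 CPM in irradiated 4 and 206 CPM in control 2, against a median of 3.13 CPM, with 3.36 CPM in irradiated 1 and 58.1 CPM in the highest of the other 15 libraries. A run of 7 in control 2 lay at 70349567 to 70590626 on chromosome 16, with 2725 CPM, beside 1852 CPM in irradiated 1 and 570 CPM in irradiated 4, and at most 4.65 CPM in any of the other 15 libraries. What the genes of these runs encode is not established here, so whether they reflect the cell types or the segment in a tissue piece was not examined.

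The 138 genes without overlap between irradiated plus formula and control were reached by 22 of 462 splits of the 12 libraries, with 778 the highest of the others. That share is just under 0.05 and was not corrected for the other comparisons counted this way, so chance is not excluded. Other divisions of the same libraries separated more genes. The distance between these groups gave p = 0.381 in the exact permutation test. Between irradiated plus formula and irradiated 31 genes did not overlap, reached by 161 of 462 splits (highest other 486), and between irradiated and control 1 gene, reached by 455 of 462 (highest other 595).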
